A study of Mus musculus with 4 samples.

How the data were processed

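Gene expression was measured on 4 Agilent 1-colour mouse arrays, 1 for each of LucKD, Tif1bKD, Hp1aKD and Hp1gKD. Per the labels, stem cells of C57BL/6 mice were sorted at 100 cells per well, kept for 24 h before transduction, exposed to lentivirus for 24 h at a multiplicity of infection of 1500 to 3000, and cultured for a further 14 days before the sort that gave the RNA. The labels do not say how many wells or animals gave the RNA of an array. LucKD was taken as the control because its name holds none of the 3 targeted genes. All 4 arrays were on 1 slide and in 1 scan per the file headers, so neither separates the groups. Each array has its own culture, sort and amplification, which cannot be told apart from its group.

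The authors scanned the arrays and extracted the spots with Agilent Feature Extraction 10.7.1.1. The scanner tables hold fluorescence intensities that, per the file headers, this software had background-subtracted within each array and had not scaled between arrays. They also hold the raw median brightness of each spot and its local background, and marks for spots that are well above background, saturated or outliers. The deposited series matrix holds 55821 probes with signal values on a linear scale. The text of the series does not give their scaling in full, so it was checked on the values: for 99.7% of the probes with a matrix value above 1 on each array (13932 to 13941 probes), the scanner intensity over the matrix value was within 0.1% of 1 constant (330, 363, 457 and 448 for LucKD, Tif1bKD, Hp1aKD and Hp1gKD), and the 75th percentile of each matrix column was 1. The authors therefore had divided each array's signal by its 75th percentile over all probes, controls included, with no centring between arrays.

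Each array had 62976 spots, of which 59305 were not controls, from 55681 probes. Outlier spots, 200 on LucKD, 199 on Tif1bKD, 171 on Hp1aKD and 157 on Hp1gKD, were left out, and 0 spots were saturated. The background-subtracted intensity was put on the log2 scale, the spots of a probe were averaged, and the 75th percentile of the array's non-control probes was subtracted. The tables have no column of gene symbols, so probes were matched through the accessions in them to a RefSeq table of symbols: 27428 probes matched 1 symbol and gave 20833 genes, 5494 of them with several probes, and 28253 probes stayed without a symbol. Of these, 16181 are named by a genome interval and are counted apart. A gene was represented by the probe with the highest mean over the 4 arrays. Its other probes were compared with it where they were well above background on both arrays. The arrays were designed on mm9 per the file headers, while the symbol table is for a later build, so no gene coordinates are given.

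A gene was compared between 2 arrays when its probe was well above background and unsaturated on both. On LucKD 12770 genes were well above background, on Tif1bKD 13049, on Hp1aKD 13160 and on Hp1gKD 13304, and 12202 were so on all 4. A gene well above background on 1 array only has a lower bound of its fold, against the higher of its own signal on the dim array and that array's lowest signal well above background (18.2 intensity units on LucKD, 18.0 on Tif1bKD, 17.0 on Hp1aKD and 17.6 on Hp1gKD). With 1 array per group no test was possible. The results are log2 differences between arrays, counts of genes past a fold limit of 2, and the percentile of a list's median among 10000 random lists of the same size, matched in 20 bins of mean expression. Lists with fewer than 5 compared members have no percentile. A percentile under 2.5 or over 97.5 describes these arrays and is not a test of a difference between groups.

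The 32 gene lists, the fold limit, the comparisons and the rule for naming genes were set before the data were examined. Named are, for each comparison, the 10 genes with the largest positive and the 10 with the largest negative difference, the 5 with the largest bound among those well above background on only 1 of the 2 arrays in each direction, the targeted genes with Cbx1, up to 4 members per list with the largest difference past the limit, and the 10 genes with the largest difference in the same direction in all 3 knockdowns. Genes past the limit in all 3 knockdowns were ranked by the smallest of their 3 differences. Genes known only by a clone, accession or predicted-gene name were passed over, and only part of the named genes is printed. Any gene outside the rule is given as chosen after its values were seen. Correlations between knockdowns were computed across the genes well above background on all 4 arrays. Because the 3 comparisons share the LucKD array, 20 simulations of unchanged arrays against a shared control were run, with the spread of repeated spots or with the spread between the closest pair of arrays.

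The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, 2 other scaling references, the series matrix values, other filters on dim probes, the mean over a gene's probes, fold limits of 1.5 and 4, outlier spots kept, and random lists matched in other ways. Normexp was meant to use the mean brightness of each spot and used the median brightness, since the tables have no column of means. In a test on simulated arrays with the spot noise of the LucKD array, genes were shifted by 1.5 or 3 log2 units on the simulated Tif1bKD array. Shifts in either direction were past the limit in 100% of 50 cases each, and 0 of 12002 unshifted genes were. Of 40 random lists of 30 genes, 92.5% lay between percentiles 2.5 and 97.5, and a list shifted by 0.5 lay at percentile 100. That test holds spot noise alone, not the spread between cultures. Its lists are of randomly drawn genes with independent noise, while genes of a real list can vary together, so it does not calibrate the percentiles of the real lists. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.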

Results

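The series measured gene expression in mouse haematopoietic progenitors after knockdown of Tif1b, Hp1a or Hp1g. Tif1b, whose gene symbol is Trim28, is a corepressor that KRAB zinc finger proteins bring to DNA. Hp1a (gene symbol Cbx5) and Hp1g (Cbx3) are heterochromatin proteins that bind methylated lysine 9 of histone H3 and bind Tif1b. Stem cells sorted from C57BL/6 mice received a lentiviral short hairpin and were cultured for 14 days with stem cell factor and thrombopoietin, each at 50 ng/ml. Progenitors that carried the GFP of the virus, were positive for c-Kit and lacked lineage markers were then sorted, and 10 ng of their RNA was amplified and labelled for each array. There were 4 arrays, 1 for each knockdown and 1 for LucKD, the group with none of the 3 genes in its name, which served as the control.

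Each array carried 55681 different non-control probes. The number well above background was 27269 on the LucKD array (49.0%), 28300 on Tif1bKD (50.8%), 29083 on Hp1aKD (52.2%) and 29201 on Hp1gKD (52.4%), and no spot was saturated. The 75th percentile of the signal, used for scaling, was 331 intensity units on LucKD, 365 on Tif1bKD, 459 on Hp1aKD and 450 on Hp1gKD. The spots of a probe printed 10 times differed by a median SD of 0.0577 to 0.0616 on the log2 scale. With 1 array per group no difference between groups has a replicate check, so every value below describes these 4 arrays and no p-value is given. The folds of named genes depend on the background correction: under normexp with quantile normalization the log2 difference had a median of 76.7% of the value given here, and none reversed. All differences are log2 values against LucKD after scaling, and "higher" or "lower" in a count means at least 2-fold between 2 arrays on which the gene was well above background.

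The targeted gene was lower on the array of its own knockdown in each case. Trim28 in Tif1bKD was at 12.1% of its LucKD level, a difference of -3.05. Cbx5 in Hp1aKD was at 28.6% (-1.80) by the brighter of its probes and at 23.3% (-2.10) by the other. Cbx3 in Hp1gKD was at 18.1% (-2.46) and 17.6% (-2.51) by its 2 probes. On the arrays of the other knockdowns these probes lay between -0.39 and 0.18. Cbx1, the HP1 paralog that was not targeted, differed by -0.39 in Tif1bKD, 0.16 in Hp1aKD and 0.17 in Hp1gKD.

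**Figure D1:**
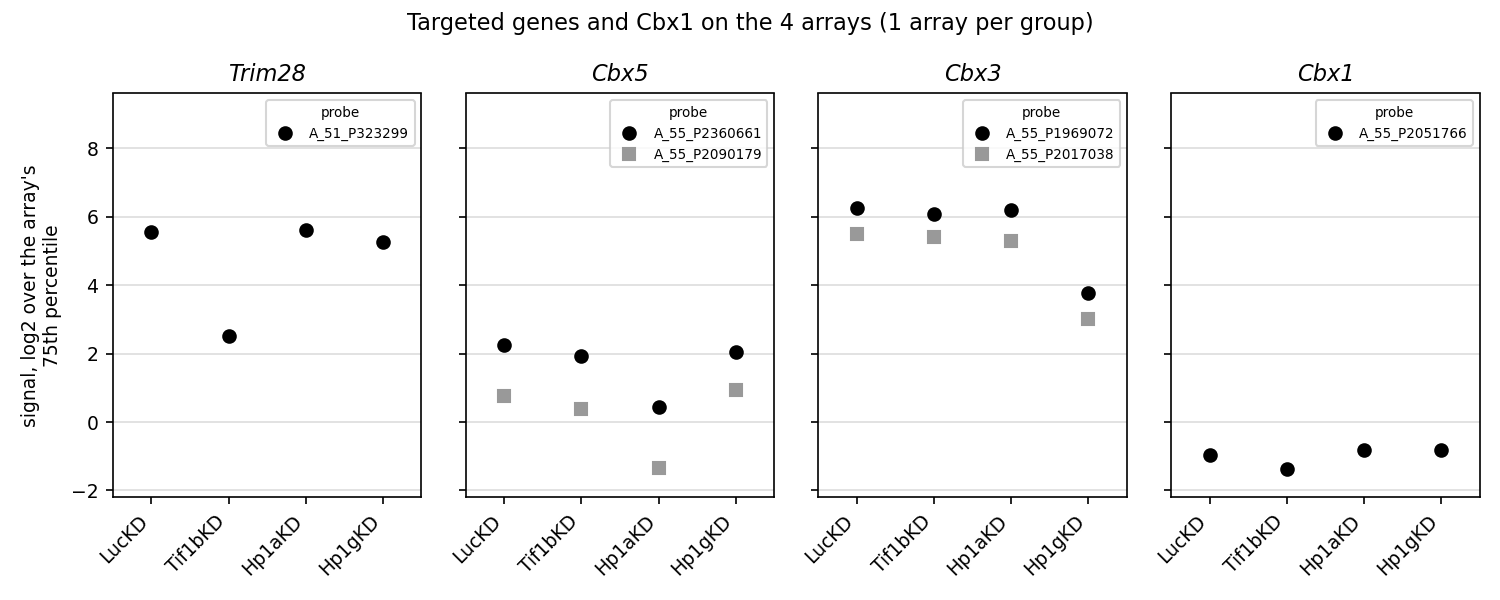
Signal of the 3 targeted genes and of Cbx1 on each array, in log2 units over the array's 75th percentile; each point is 1 probe on 1 array, and circles and squares are different probes of a gene. Trim28 is lowest on Tif1bKD (2.51, against 5.26 to 5.60 on the other arrays), Cbx5 on Hp1aKD and Cbx3 on Hp1gKD.

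Interferon-stimulated genes and myeloid genes were higher in Tif1bKD than in LucKD, and cell division genes were lower. Of 38 interferon-stimulated genes compared, 16 were higher and 0 lower, and all 38 lay above 0. Their median difference was 0.92, above all 10000 random lists of matched expression. Oas2, which makes the activator of RNase L, was 9.75-fold higher, the chemokine gene Cxcl10 9.32-fold, Ifit1 8.30-fold and the transcription factor gene Irf7 6.02-fold. Among 20 neutrophil and granulocyte genes 4 were higher and 0 lower (median 0.40, above all 10000 random lists), among them Lcn2 (lipocalin, an iron-siderophore binding protein, 21.7-fold), Hp (haptoglobin, 8.27-fold), the transcriptional repressor gene Gfi1 (7.00-fold) and Lyz2 (lysozyme, 2.84-fold). A further 6 genes of this list were well above background on the Tif1bKD array alone of the 2, with Stfa1 at least 55.9-fold higher.

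Monocyte, macrophage and dendritic cell genes followed in Tif1bKD, with 8 of 28 higher and 1 lower (median 0.28). The macrophage surface gene Adgre1 was 7.40-fold higher, the class II gene H2-Eb1 4.95-fold, Cybb of the phagocyte oxidase 4.29-fold and the integrin gene Itgax 3.93-fold. Of 14 T and NK lymphoid genes 3 were higher and 1 lower (median 0.30): Ccl5 was 11.2-fold, Thy1 (also on the fibroblast and stromal list) 9.52-fold and Trat1 7.80-fold higher, and Klrd1 2.57-fold lower. Mast cell, basophil and eosinophil genes had 1 of 18 higher, Il6 (4.61-fold), and a median of 0.19, at percentile 99.8 of the random lists; the median was -0.15 without a detection filter. Immediate early genes, which respond to stimuli without new protein synthesis, had a median of 0.53 with 5 of 25 higher and 0 lower, including Atf3 (3.73-fold), Fosb (3.06-fold) and Junb (2.76-fold). Stress response genes had 4 of 27 higher and a median of 0.08, percentile 99.9, led by Nupr1 (5.16-fold) and the arginine transporter gene Slc7a3 (3.48-fold). Of 10 Hox genes compared 3 were higher (median 0.37, percentile 98.9, or 96.85 with random lists matched on the LucKD signal), Hoxb2 by 2.95-fold, Hoxa7 by 2.23-fold and Hoxa3 by 2.19-fold.

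Mitosis genes had a median of -0.50 in Tif1bKD, and all 30 lay below 0 though none reached 2-fold. DNA replication genes had a median of -0.26 with 4 of 34 above 0, and respiratory chain genes a median of -0.31 with 2 of 80 above 0. All 3 medians lay at or under percentile 0.02 of the random lists. Megakaryocyte and platelet genes were lower (median -0.34, percentile 0.01), with 3 of 26 at least 2-fold lower and 1 higher: Clec1b, a platelet activation receptor gene, by 3.47-fold (-1.80 and -1.81 by 2 of its probes but -0.57 by the other), Gp1bb by 2.84-fold and Nrgn by 2.34-fold. The list's median was about as low in the other knockdowns (-0.35 in Hp1aKD and -0.31 in Hp1gKD) and lay between -0.04 and -0.0025 directly between knockdown arrays, so a high LucKD array may account for the medians. It would not account for the members at least 2-fold lower in Hp1aKD than in Hp1gKD, 5 of 27 with 0 higher (percentile 0.85). Setdb1, the H3K9 methyltransferase gene whose product Tif1b recruits, was 3.09-fold higher.

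Across all genes, 404 were higher and 185 lower in Tif1bKD among 12367 compared, 663 were well above background on Tif1bKD only and 389 on LucKD only. The largest positive differences belonged to Gstt1, a glutathione transferase gene (29.6-fold), Lcn2, Bcl3 of the NF-kappa-B pathway (21.2-fold), Cyp2b10 (20.8-fold), Csta2 (19-fold) and the beta-globin genes Hbb-b2 (16.6-fold) and Hbb-bt (14.0-fold), whose near-identical transcripts a probe may not separate. Hbb-b2 was the 1 higher gene of 18 erythroid genes, whose median was -0.23. The largest negative differences belonged to Vmn1r219 (28.9-fold lower), Rims1 (21.9-fold), Crisp3 (17.8-fold), Gpam (15.9-fold) and Ccdc146 (15.8-fold). Trim28 was also among the 10 genes with the largest negative difference. LucKD had the lowest scaling signal and the fewest probes well above background of the 4 arrays, which bears on every count of genes above background on 1 array only.

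In Hp1aKD, genes of differentiated blood lineages and immediate early genes were lower than in LucKD. Monocyte, macrophage and dendritic cell genes showed this most, with 15 of 26 lower, 0 higher and a median of -1.17, below all 10000 random lists. The class II gene H2-Ab1 was 8.44-fold lower (its second probe gave -3.17 against -3.08), the invariant chain gene Cd74 8.12-fold, the fractalkine receptor gene Cx3cr1 6.09-fold and Ly86 5.27-fold. Neutrophil and granulocyte genes had 5 of 19 lower and a median of -0.55, among them Hp (4.36-fold), Cebpe (4.03-fold), Elane (neutrophil elastase, 2.39-fold) and Lcn2 (2.24-fold). Of 17 erythroid genes 6 were lower (median -0.70), including the erythroid transcription factor gene Klf1 (3.02-fold), the erythropoietin receptor gene Epor (2.95-fold) and Spta1 of the red cell skeleton (2.40-fold). Mast cell, basophil and eosinophil genes had 6 of 16 lower (median -0.49), with Hdc, which makes histamine, 4.52-fold lower and Fcer1a 2.98-fold lower.

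Megakaryocyte and platelet genes had 8 of 27 lower, 1 higher and a median of -0.35 in Hp1aKD. Thbs1 (thrombospondin) was 9.03-fold lower and Ppbp 6.90-fold lower, while Alox12 was 3.19-fold higher. T and NK lymphoid genes had 3 of 13 lower: Cd7 (5.93-fold), Ccl5 (5.60-fold) and Klrd1 (4.82-fold), with a median of -0.35 at percentile 0.38. Immediate early genes had 11 of 25 lower, 0 higher and a median of -0.77, with Atf3 7.59-fold, Egr2 4.62-fold, Klf2 3.30-fold and Fos 2.78-fold lower. Fibroblast and stromal genes, of which only 9 could be compared, had a median of -0.63 with 1 lower, Col1a2 (2.03-fold). Interferon-stimulated genes had a median of -0.02 and 2 of 36 lower, inside the central 95% of the random lists.

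Other gene groups were higher in Hp1aKD. DNA replication genes had a median of 0.32 with 33 of 34 above 0, above all 10000 random lists, although Cdc45 (2.03-fold) was the 1 gene past 2-fold. p53 target and cell cycle inhibitor genes had a median of 0.36, also above all random lists, with 4 of 26 higher and 2 lower. Zmat3 was 3.55-fold, Phlda3 2.85-fold and Pvt1 2.77-fold higher (0.89 by the other probe of Pvt1), and Perp was 2.54-fold lower. Haematopoietic stem cell genes had a median of 0.21, at percentile 99.1, with 2 of 26 higher (Esam by 2.32-fold and Sult1a1 by 2.07-fold) and 2 lower (Slamf1 by 2.72-fold and Hoxb5 by 2.34-fold).

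Lower genes outnumbered higher ones in Hp1aKD, 429 to 107 among 12407 compared, with 734 genes well above background on Hp1aKD only and 351 on LucKD only. Hmox1 (haem oxygenase) was 29.8-fold lower by its brighter probe and differed by -2.83 by the other. Slc16a3, a lactate exporter gene, was 12-fold lower, with -3.58 and -3.54 by its 2 probes. Lgals3 (galectin-3) was 11-fold, Ankrd37 10.6-fold and the collagen prolyl hydroxylase gene P4ha2 10.0-fold lower. The genes with the largest positive differences were Zfp383 (8.72-fold), Tmigd3 (8.0-fold), Sh2d2a (6.90-fold) and Eps8l1 (6.55-fold).

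Stromal genes, some stem cell genes and p53 target genes were higher in Hp1gKD, and immediate early genes were lower. Of the 9 fibroblast and stromal genes compared 6 were higher and 1 lower, with a median of 1.63, above all 10000 random lists: the matrix metalloproteinase gene Mmp2 was 17.8-fold, Col1a2 3.66-fold, Thy1 (also on the T and NK lymphoid list) 3.34-fold and Fstl1 3.32-fold higher. The list holds 25 genes on the array, and with no detection filter its median was -0.54. Haematopoietic stem cell genes had 7 of 26 higher and 1 lower (median 0.18, percentile 99.8). Procr, the endothelial protein C receptor gene that marks stem cells, was 8.13-fold higher, Robo4 3.83-fold, Ly6a (Sca-1) 3.05-fold and Sult1a1 2.86-fold. In Tif1bKD the stem cell list had 3 of 25 higher, 1 lower and a median of -0.15 (percentile 10.4), with Ly6a 4.51-fold higher. p53 target and cell cycle inhibitor genes had 6 of 26 higher, 1 lower and a median of 0.45, above all random lists, with Zmat3 4.74-fold, Phlda3 2.45-fold and Pvt1 2.36-fold higher (0.66 by its other probe) and Btg2 2.74-fold lower. Of 23 imprinted genes 4 were higher and 2 lower (median 0.05, percentile 80.65). Dlk1 was 14.6-fold higher, with 3.87 and 3.91 by its 2 probes, Grb10 2.58-fold higher and Ascl2 2.20-fold lower.

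Immediate early genes in Hp1gKD had 7 of 25 lower, 1 higher and a median of -0.71, below all random lists, with Klf2 3.61-fold, Zfp36 3.41-fold, Egr2 3.07-fold and Atf3 3.04-fold lower. T and NK lymphoid genes had a median of -0.52 with 3 of 13 lower (Cd7 by 3.31-fold, Ccl5 by 2.93-fold and Klrd1 by 2.66-fold) and 2 higher. Megakaryocyte and platelet genes (median -0.31) and mast cell, basophil and eosinophil genes (median -0.37) both lay at percentile 0.05, with 2 of 27 lower, 1 of 27 higher and 1 of 18 lower. Neutrophil and monocyte lists had medians of -0.20 and -0.12 inside the central 95% of the random lists, with Gfi1 5.51-fold and Spib 3.00-fold higher and Cebpe 2.45-fold and Ltb4r1 2.20-fold lower. Interferon-stimulated genes had a median of 0.26, above all random lists, with 1 of 37 higher, Oasl2 (2.08-fold). Birc5 (survivin), an inhibitor of apoptosis that acts in mitosis, was 2.57-fold lower, and its 3 probes gave -1.36, -1.39 and -1.45.

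For Hp1gKD 298 genes were higher and 250 lower among 12442 compared, 836 were well above background on Hp1gKD only and 315 on LucKD only. With normexp background correction and quantile normalization the split was 159 higher and 80 lower. At a fold limit of 1.5 it turned to 763 higher and 959 lower, and without a detection filter to 954 higher and 1110 lower. The largest positive differences belonged to Npdc1 (22.8-fold), the transcription factor gene Tead2 (21.1-fold), Mmp2, Arhgef28 (16.0-fold) and Dlk1, and the largest negative ones to Gpam (14.7-fold lower), Syne1 (10.2-fold by 1 probe, but 0.30 by the other), Foxi3 (9.38-fold) and Rnf165, which differed by -3.42.

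Replication-dependent histone genes were lower on all 3 knockdown arrays, with medians of -0.52 in Tif1bKD, -0.47 in Hp1aKD and -0.61 in Hp1gKD, each below all 10000 random lists. At most 3 of the 47 members were past 2-fold on any array. All 3 values use the 1 LucKD array, and a high LucKD array alone would give them: directly between knockdown arrays the medians were -0.0012 (Tif1bKD against Hp1aKD), 0.12 (Tif1bKD against Hp1gKD) and 0.15 (Hp1aKD against Hp1gKD). Ribosomal protein genes had medians of -0.20, -0.34 and -0.38, which quantile normalization brought to between -0.01 and 0.02 with or without normexp, so their size depended on the scaling; with normexp the sign turned in Hp1aKD and Hp1gKD. Among the remaining lists, zinc finger genes lay at percentile 100 in Hp1gKD with a median of only 0.07 and 6 of 326 higher and 6 lower, and in Tif1bKD Zfp157 was 8.41-fold higher by 1 probe and differed by -0.38 by the other. Hox genes in Hp1gKD had a median of 0.34 (percentile 98.0, or 95.6 with random lists matched on the LucKD signal), which was -0.51 with no detection filter. Muscle genes (median -0.80, 9 compared), cholesterol synthesis genes (-0.25) and olfactory receptor genes (-0.39) lay under percentile 2.5 in Hp1gKD. The complex and H3K9 methylation machinery, B lymphoid, imprinted, germline, neuronal, liver, epithelial and endothelial lists lay inside the central 95% of matched random lists in all 3 comparisons. Against unmatched random lists, B lymphoid genes in Tif1bKD (percentile 1.99), germline genes in Hp1aKD (1.82) and Hp1gKD (1.54), neuronal genes in Hp1aKD (0.68) and epithelial genes in Hp1gKD (1.04) lay below it. Too few 2-cell embryo and protocadherin genes could be compared with LucKD for a percentile, at most 4 and 3.

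**Figure D2:**
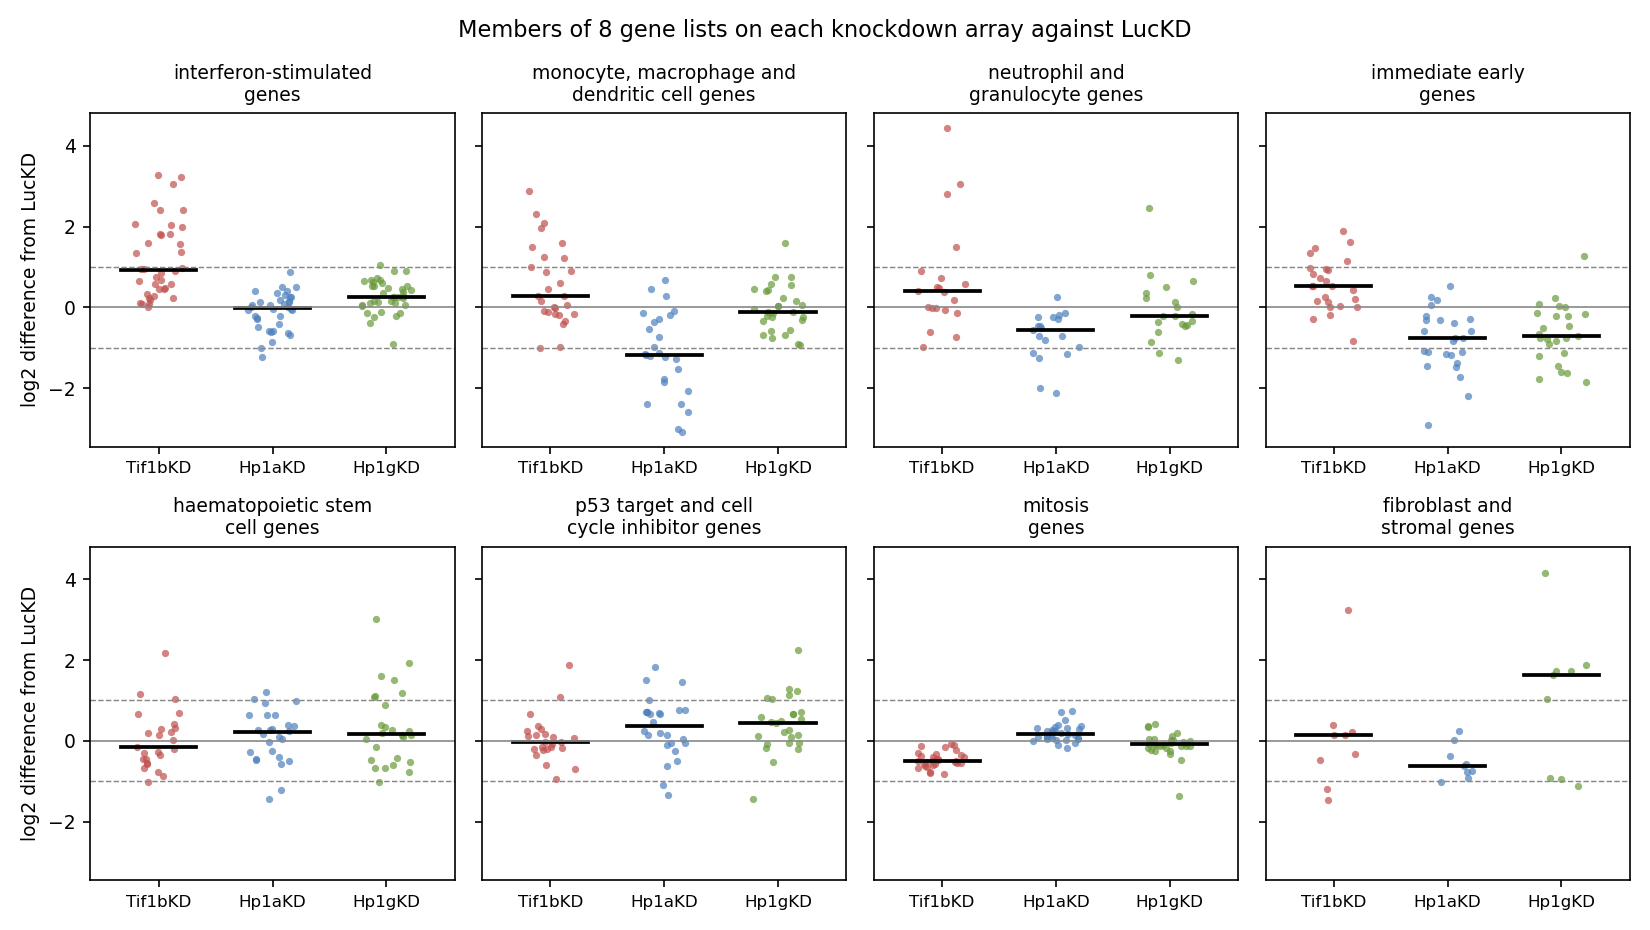
Log2 difference from LucKD of each compared member of 8 gene lists, for each knockdown array; each point is a gene, black lines are list medians, and dashed lines mark 2-fold. Interferon-stimulated genes lie highest in Tif1bKD (median 0.92), and monocyte, macrophage and dendritic cell genes lowest in Hp1aKD (median -1.17).

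Compared directly, Tif1bKD and Hp1aKD were the pair with most genes past 2-fold, 780 higher and 292 lower in Tif1bKD among 12481. Monocyte, macrophage and dendritic cell genes had 16 of 26 higher in Tif1bKD (median 1.74), immediate early genes 18 of 25 (median 1.27) and interferon-stimulated genes 17 of 36 (median 0.93). Against Hp1gKD, 591 genes were higher and 395 lower in Tif1bKD, with 15 of 25 immediate early genes (median 1.43) and 13 of 38 interferon-stimulated genes (median 0.73) higher. Between the HP1 knockdowns, 98 genes were higher and 480 lower in Hp1aKD. Of 26 monocyte, macrophage and dendritic cell genes 11 were lower in Hp1aKD than in Hp1gKD (median -0.85), all 34 DNA replication genes lay above 0 (median 0.42), and immediate early genes had a median of 0.02 with 5 of 25 lower.

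The differences from LucKD of Hp1aKD and Hp1gKD correlated across 12202 genes with r = 0.53 (Spearman 0.60), those of Tif1bKD and Hp1gKD with 0.18 (0.22), and those of Tif1bKD and Hp1aKD with -0.01 (0.07); genes are not independent replicates. All 3 comparisons use the same LucKD array, and simulated unchanged arrays against a shared control gave r = 0.50. Independent noise of equal spread on every array gives this value by construction, so it does not show how much of the 0.53 comes from LucKD. The covariance was 0.111 for the HP1 knockdowns, 0.0390 for Tif1bKD and Hp1gKD and -0.00288 for Tif1bKD and Hp1aKD. The covariance that the shared array adds was 0.00355 in simulations with spot noise alone and 0.102 to 0.103 with the spread of the closest pair of arrays. Hp1aKD and Hp1gKD shared 116 lower genes and 37 higher genes, where independent lists would share 7.26 and 2.04. The simulation with the closest pair's spread gave 104 and 106. It put 288 genes past 2-fold in each direction, while Hp1aKD had only 92 higher genes, so the observed overlap could not reach 106. The closest pair was Hp1aKD and Hp1gKD themselves, so the spread used also holds any difference between these knockdowns. Tif1bKD and Hp1aKD had 76 genes higher in the first and lower in the second, against 12.3 for independent lists, and 15 higher in both. Part of each overlap in the same direction may come from the shared control, which cannot be split and which works against an overlap in opposite directions.

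**Figure D3:**
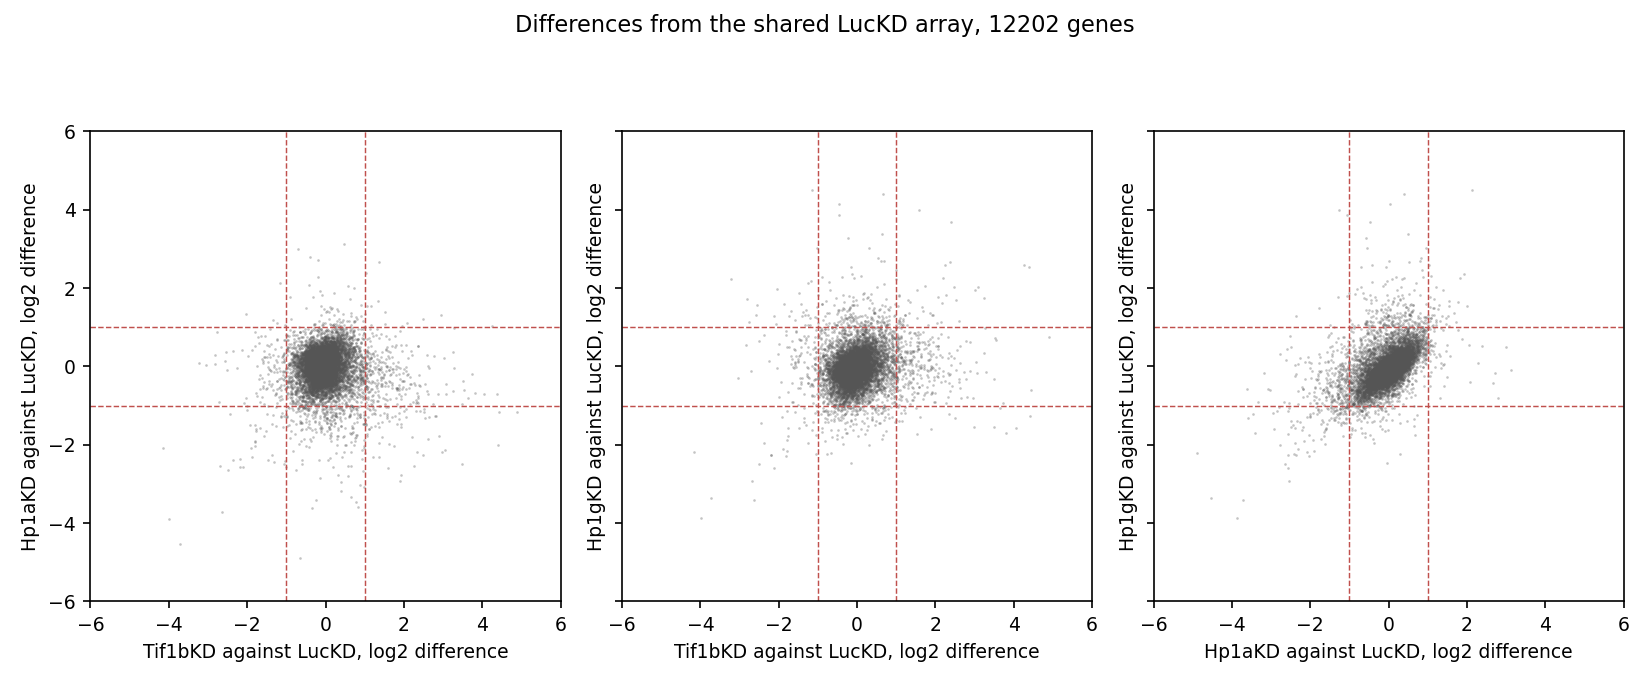
Log2 difference from LucKD of each gene well above background on all 4 arrays (12202 genes), for each pair of knockdowns; points are genes and dashed lines mark 2-fold. The Hp1aKD and Hp1gKD differences lie along the diagonal (r = 0.53), while those of Tif1bKD and Hp1aKD do not (r = -0.01).

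All 3 knockdowns shared 8 higher and 27 lower genes. Simulated unchanged arrays with the closest pair's spread gave 80.6 in each direction. They had 288 genes past 2-fold each way, against 92 higher in Hp1aKD and 169 lower in Tif1bKD. The 80.6 is therefore no measure of what chance would give on these arrays. Ranked by the smallest of their 3 differences, the lower genes were led by Gpam (a glycerolipid synthesis gene, 14.7- to 15.9-fold lower), Syne1, Rnf165, Gpd1l and Dll3, and the higher ones by Macroh2a3 and Alox12. All 3 differences of a gene use its 1 LucKD value, and a high value there alone would give a lower gene. Gpam was at 0.12 on LucKD and at -3.87, -3.76 and -3.76 on Tif1bKD, Hp1aKD and Hp1gKD. Dll3 was at -1.47 on LucKD and at -3.97, -4.11 and -3.97. The second probe of Syne1 differed by -1.02 in Tif1bKD, -1.12 in Hp1aKD and 0.30 in Hp1gKD, so in Hp1gKD it did not match the first. Other probes of genes past 2-fold were counted only where well above background on both arrays. These were 85 probes of 78 genes in Tif1bKD, 88 of 78 in Hp1aKD and 93 of 82 in Hp1gKD. Of them, 56.5%, 55.7% and 41.9% were past 2-fold the same way, and 14.1%, 6.82% and 11.8% had the opposite sign. The second probes of Tead2, Arhgef28, Alox12, Dll3 and Rnf165 did not meet this condition in any comparison with LucKD, so they gave no check. The same simulation gave 288 genes past 2-fold in each direction among the 12202, against observed values of 369 and 169 in Tif1bKD, 92 and 408 in Hp1aKD and 271 and 217 in Hp1gKD. Spot noise alone gave 0.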

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

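The tests of expression that all 3 knockdowns remove, of fewer differentiated cells, of low interferon-stimulated genes on LucKD and of more monocytes, and the separate count of interval probes, were chosen only after the results were seen.

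Probes named by a genome interval, without a gene symbol, are outside the gene counts and were examined because more of them were well above background on each knockdown array than on LucKD. Of 16181 such probes, 842 were well above background on Tif1bKD and not on LucKD, with 451 the other way. The numbers were 1171 and 353 for Hp1aKD, and 1094 and 380 for Hp1gKD. Probes with a gene symbol showed an excess in the same direction: 911 against 487, 1016 against 411 and 1170 against 365. Among interval probes well above background on both arrays, 112 of 4846 were at least 2-fold higher in Tif1bKD and 105 lower, 85 of 4944 higher in Hp1aKD and 200 lower, and 83 of 4917 higher in Hp1gKD and 194 lower. As shares these were 2.31% and 2.17%, 1.72% and 4.05%, and 1.69% and 3.95%. For probes with a gene symbol the shares were 3.00% and 1.49%, 1.17% and 3.14%, and 2.26% and 1.89%. Median differences of the interval probes well above background on both arrays were -0.04, -0.20 and -0.19, against -0.06, 0.05 and -0.04 for such probes with a symbol. Chosen after its values were seen, the interval 109044453 to 109045618 of chromosome 12 (mm9) was at 4.25 in Hp1aKD, and 30170306 to 30223193 of chromosome 16 at 4.15 in Hp1gKD, in log2 units against LucKD. The interval 108153471 to 108159346 of chromosome 8 was lower in all 3 knockdowns (-4.05 in Tif1bKD, -4.43 in Hp1aKD and -4.46 in Hp1gKD), as a high LucKD value alone would give. No explanation of these differences was tested.

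On the LucKD array 63 genes were at least 4-fold above all other arrays and well above background there alone, among them Olfr304, Hopx, Ccdc85c and Gk2. Each of the other arrays had such genes too, 61 on Tif1bKD, 76 on Hp1aKD and 71 on Hp1gKD, and the LucKD number was 0.909 times the mean of the other 3, as chance loss or gain of transcripts in amplifying 10 ng of RNA would give. Of 12 other probes of the LucKD genes 0% were at least 2-fold brighter on LucKD, which faults of single spots or probes would also give. On the other arrays the share was 22.7% of 22 probes for Tif1bKD, 4% of 25 for Hp1aKD and 9.52% of 21 for Hp1gKD. Expression that all 3 knockdowns remove cannot be told apart from these for the 63 genes, since each group has 1 array. A gene seen on a single array is thus a weak basis for a difference between groups.

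The lower monocyte, macrophage and dendritic cell genes in Hp1aKD (median -1.17) were weighed against array scaling, which is excluded as the whole cause: the highest median under another scaling or background correction was -0.68. Fewer differentiated cells in the sorted fraction may explain the difference, since 4 of 4 other lineage lists (neutrophil, mast cell, megakaryocyte and erythroid) lay below percentile 2.5 and the stem cell list lay at 99.1, although the megakaryocyte list had about the same median in Tif1bKD (-0.34) and Hp1gKD (-0.31) as in Hp1aKD (-0.35), as a high LucKD array would give, while directly against Hp1gKD it had 5 of 27 lower and 0 higher in Hp1aKD (percentile 0.85). The stem cell list, 12 of whose 30 genes are also on another list, lay as high in Hp1gKD (percentile 99.8). Directly against Hp1gKD its median in Hp1aKD was -0.05 (percentile 3.81), with 0 of 28 higher and 3 lower. Tif1bKD lay below Hp1aKD (-0.30, percentile 1.135), so a low LucKD array may account for part of the rise. The neutrophil, mast cell and erythroid lists were also lower in Hp1aKD than in Hp1gKD, each at percentile 0. The sort kept cells with c-Kit and without lineage markers. It would remove mature cells that lack c-Kit or carry such markers, but no others. Yet the abundant H2-Ab1 went from 2.51 on LucKD to -0.56 on Hp1aKD and Cd74 from -1.42 to -4.45 (log2 over the 75th percentile). Of the 39 monocyte genes on the array 0 belong to another list, and how many of them progenitors express was not determined. Lower expression within the same cells after loss of Hp1a, and a difference between single cultures, stay open and untested.

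The higher interferon-stimulated genes in Tif1bKD (median 0.92) kept a median of at least 0.82 under the other scalings and background corrections, which argues against array scaling. Low interferon-stimulated genes on LucKD are excluded as the whole cause, as the medians directly against Hp1aKD and Hp1gKD were 0.93 and 0.73. They may be a part of it: 30 of 36 genes lay above 0 against Hp1aKD and 28 of 38 against Hp1gKD, but all 38 against LucKD. More monocytes and macrophages cannot be told apart for this list: the monocyte list's median was 0.28, below that of the interferon list, but its upper quartile, 1.23, was above it. The sort would remove such cells only where they lack c-Kit or carry lineage markers. The 2 lists share 0 of their 40 and 39 genes, and H2-Eb1, Adgre1 and Cybb of the monocyte list were higher in Tif1bKD. An interferon response to the knockdown of Tif1b, and a difference between single cultures, stay open and were not tested.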

How the results depend on the processing

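Every alternative here was planned, except that the separate count of interval probes and the HIF list were chosen after the data were seen. No paired analysis was possible because the groups share only replicate number 1. Leaving out a replicate was not possible with 1 array per group.

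Counts of higher and lower genes, 404 and 185 in Tif1bKD, 107 and 429 in Hp1aKD and 298 and 250 in Hp1gKD, stayed within 1.5 times under the 3 scalings without normexp, the series matrix, outlier spots kept, the filter on all 4 arrays and the mean of probes. With normexp and quantile normalization they were 257 and 93, 38 and 206, and 159 and 80; the cause was not tested. With dim signals set to the floor, which adds genes seen on 1 array, they were 632 and 367, 283 and 713, and 538 and 468. With no detection filter, which adds undetected genes, they were 1241 and 870, 661 and 1368, and 954 and 1110, so lower genes then outnumbered higher ones in Hp1gKD. By construction, a fold limit of 1.5 gave 889 and 727, 602 and 1099, and 763 and 959, and a limit of 4 gave 97 and 35, 15 and 79, and 43 and 26. Lower genes outnumbered higher ones in Hp1gKD at 1.5 too.

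Over these alternatives 844 list medians moved by less than 0.188, the tolerance from the spread between probes of a gene, 51 moved further and 5 reversed. Without a detection filter the mast cell median in Tif1bKD was -0.15 (0.19 before), and in Hp1gKD the fibroblast median was -0.54 (1.63) and the Hox median -0.51 (0.34). Under normexp and quantile normalization the ribosomal protein median was 0.015 in Hp1aKD (-0.34) and 0.017 in Hp1gKD (-0.38). The cause of these reversals was not tested. Values of named genes moved in 172 cases, did not in 2033, and reversed in none. Under normexp with quantile normalization 155 of 223 moved, all 155 towards 0, with a median of 76.7% of the main log2 difference (quartiles 59.2% and 90.7%). List percentiles kept their side of the limits in 161 cases and not in 19. Hox genes in Tif1bKD and Hp1gKD and ribosomal protein genes in Tif1bKD came inside the limits with lists matched on the LucKD signal, and the others went outside them. The 9 correlations and overlaps between knockdowns were recomputed only under quantile normalization and with the series matrix, and stayed within 0.1 (correlations) or 1.5 times (overlaps) under both. No scaling moved the all-gene median by over 0.1.

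Signal over background limits the comparison of dim genes: those under about 18.2 intensity units on LucKD have no fold, only a bound.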

Other observations

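The list of HIF target and glycolysis genes was written only after ranked genes were seen. The members printed with their values, and the genes given below as well above background on a knockdown array and not on LucKD, were chosen after their values were seen. The prediction for the list members not among those first seen was written before their values.

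Slc16a3, Ankrd37 and P4ha2, among the most reduced genes in Hp1aKD, are targets of hypoxia-inducible factor (HIF), so a list of 40 HIF target and glycolysis genes was drawn up. All 38 compared members lay below 0 in Hp1aKD, 21 of them at least 2-fold lower, with a median of -1.07. Without the 5 members first seen, 16 of 33 were lower, the median was -0.94 and its percentile among the 10000 matched random lists was 0, which fits a general fall of HIF target and glycolysis genes beyond those first seen. The median stayed between -0.94 and -1.11 under the other scalings and background corrections. Eno1 was 2.79-fold, Slc2a1 2.89-fold, Aldoa 2.57-fold, Vegfa 2.39-fold, P4ha1 5.09-fold and Egln3 4.56-fold lower, while Car9 (-0.05) hardly differed. Hp1gKD had a median of -0.64 (-0.43 under normexp and quantile normalization) with 37 of 38 below 0, 5 lower and a percentile of 0, and Tif1bKD one of 0.21 with 1 of 39 higher, at percentile 100. Whether the activity of HIF itself differed was not tested. Oxygen and cell density in the single wells, and the mix of cell types, stay open and were not tested.

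Some genes were well above background on a knockdown array and not on LucKD. In Tif1bKD, S100a9 was at least 14.1-fold, S100a8 at least 4.28-fold, Cd209a at least 19.3-fold and the 2-cell embryo gene Zscan4c at least 16.0-fold higher. Zscan4c was well above background on Hp1gKD too, at least 1.04-fold higher. In Hp1gKD, the cell cycle inhibitor gene Cdkn2a was at least 15.9-fold, the endothelial gene Cdh5 at least 17.4-fold, the imprinted gene Meg3 at least 6.99-fold and Rhox5 at least 5.12-fold higher, and Meg3 was well above background on Tif1bKD too, at least 2.74-fold higher. Each array, LucKD included, had 61 to 76 genes at least 4-fold above all others and seen on that array alone, so such values on 1 array have no check here.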
